A study of Mus musculus with 4 samples.

How the data were processed

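RNA of single mouse liver cells was measured in 4 libraries, 1 each for the control, low-AFP, high-AFP and HCC groups. Per the labels, livers were perfused with collagenase, parenchymal cells were purified on a 30% Percoll gradient, non-parenchymal cells were enriched for live cells by fluorescence-activated sorting, and both were mixed 1:1 before loading with a 10x Genomics 3' kit (version 2 per the labels). Sequencing used an Illumina HiSeq 4000 with paired reads of 100 bases. The titles give 15 months and the age field 17 months. The submitters' processing notes name Cell Ranger, R 3.0, Seurat 3 and the mm9 build, and the matrix headers name Cell Ranger 3.0.2. The deposited matrices hold UMI counts per gene and barcode, as whole numbers, for 31053 genes with Ensembl identifiers. Of these identifiers, 30934 are also in GENCODE M21, 30468 with the same symbol. No coordinate was used, so the build does not enter any value. The groups came from the titles and the AFP labels, since the title and the file name of the high-AFP library differ in the diet they name.

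Barcodes were kept with at least 300 genes, at least 500 UMIs and at most 30% mitochondrial UMIs. Doublets were scored per library with Scrublet in scanpy 1.11.5, and barcodes above its automatic threshold were removed: 169 in control, 30 in low-AFP and 104 in high-AFP. In HCC the automatic threshold marked 0.037% of barcodes, under the 0.5% minimum set for it, so the 572 barcodes of highest score were removed, at an expected rate of 0.8% per 1000 barcodes. That rate would have removed 565, 397 and 783 barcodes in control, low-AFP and high-AFP, so doublet removal was stricter in HCC than in the others. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen across libraries, and 30 principal components with 15 neighbours were clustered by Leiden at resolution 1 (leidenalg 0.10.2), with no integration of libraries because library and group coincide. This gave 27324 cells in 49 clusters. Clusters were named by fixed marker lists for 17 cell classes, with at least 3 markers and a check of the 10 leading genes of each cluster, and 6 clusters stayed unnamed.

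UMIs of all cells of a class in a library were summed and expressed as counts per 1000000 nuclear-encoded UMIs (CPM). Log2 folds were taken after adding 10 CPM to each value. Because each group was 1 library, no test, p or standard error was computed. Sums of counts carry exact Poisson intervals and shares of cells exact (Clopper-Pearson) binomial intervals, each at 95% and covering counting error only. Classes with fewer than 50 cells in either library were not compared. A fold against 0 counts was computed against a floor of 3 counts, and a fold against 1 to 3 counts is given as a ratio with its interval. The 5 comparisons were low-AFP with control, high-AFP with control, high-AFP with low-AFP, HCC with control and HCC with high-AFP. Comparisons that share the control library are not independent, and no overlap or correlation between them was computed. For 42 fixed gene lists, members with at least 10 CPM in either library were counted when at least 2-fold higher or lower, and the list median was placed among 10000 random lists of the same size matched on expression in 20 bins (seed 1). The stellate cell and fibrogenic lists have no result, because mesenchymal-like cells were too few outside control.

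The cell filters, marker and gene lists, comparisons, rules and most alternatives were chosen before the data were examined. Genes were named by rule. In hepatocyte-like cells the rule took the 12 most higher and 12 most lower genes by log2 fold, among genes with at least 50 CPM and 50 UMIs in the higher library and a CPM there of at least 0.1 times that in any other class. In other classes it took up to 5 each way for low-AFP, high-AFP and HCC against control, with a CPM of at least 2 times that of the hepatocyte-like class, and not all of these are printed. A gene that the rule took in hepatocyte-like cells is not reported here. Mitochondrial, ribosomal protein, haemoglobin, antigen receptor, Xist, Y-linked and unnamed model genes were left out. Afp, the 2 to 4 members of each described list with the largest folds, and leading genes of a cluster were named as well. Over all kept cells, Xist had at most 7 UMIs in any library, and the Y-linked gene Ddx3y was at 106, 83.8, 83.2 and 82.9 CPM in control, low-AFP, high-AFP and HCC.

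The gene and list rules were tested on simulated data, in which 200 genes of each comparison were given a known fold, 50 per fold size. Only hepatocyte-like counts were simulated. The changed genes were drawn from those with a mean of at least 2 times the 10 CPM minimum, up to a fixed upper limit. Genes with a true 4-fold difference passed the 2-fold rule in 98%, 96%, 100%, 98% and 100% of cases in low-AFP with control, high-AFP with control, high-AFP with low-AFP, HCC with control and HCC with high-AFP, and genes with a true 8-fold difference in 100% in each. Genes with a true 2-fold difference passed in 2%, 0%, 4%, 4% and 8%, because the added 10 CPM shrinks folds, and genes with no or a 1.5-fold difference passed in 0%. Among 100 unchanged lists, 3, 7, 3, 5 and 9 lay outside the percentile range. The simulated counts held Poisson error alone, without variation between cells, clusters or animals, and the members of unchanged lists were drawn independently. These rates are therefore not rates of false calls in the real libraries. At the levels drawn, a true 4-fold difference stays at 2-fold or more after the added 10 CPM. The high pass rates thus followed from the choice of genes, and they do not cover changed genes of lower level or other cell classes. Alternatives covered the mitochondrial limit, the UMI minimum, doublet removal, Leiden resolution, CPM over all UMIs, trimmed-mean (TMM) scaling with edgeR 4.0.16 in R 4.3.3, equal weight per cell, thinning to 1000 UMIs, the pseudocount and the CPM minimum. The 4 alternatives chosen after seeing the data were the expected doublet rate in every library, unnamed hepatocyte-marker clusters added, cluster 4 alone, and the class without cluster 46. Values were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and plots were drawn with matplotlib 3.10.9. Raw reads and spliced counts were not used here.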

Results

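Single-cell 3' RNA libraries were made from mouse liver in 4 groups: control, low-AFP, high-AFP and HCC (hepatocellular carcinoma). The series title names progression from obesity to liver cancer in C57BL/6 mice on a CD-HFD, so the comparisons ask how liver cells differed with diet, with the AFP label and with tumour. Each group was 1 library, so there were no replicates: no test was made, and every difference describes these 4 libraries only. The protocol, given in the same words for all 4 libraries, mixed purified parenchymal and live-sorted non-parenchymal cells at a 1:1 ratio, and the source of the HCC library is given as a suspension from the tumour region. The titles call the control library a control diet library and the low-AFP library a CD-HFD library. The high-AFP library is called a control diet library in its title and a CD-HFD library in its file name, so the groups are named here by the AFP label and not by diet. The deposited values were UMI counts. Library totals were 71957655 UMIs over 11113 barcodes in control, 80505127 over 9257 in low-AFP, 97393862 over 11539 in high-AFP and 65326793 over 8929 in HCC. After filtering, 6190, 5329, 8373 and 7432 cells remained in control, low-AFP, high-AFP and HCC, with median depths of 5415, 7357, 6296 and 4666 UMIs. More than 30% mitochondrial UMIs removed 42.7% of the barcodes in control, 42.0% in low-AFP, 26.5% in high-AFP and 8.19% in HCC.

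Cell types were named from fixed marker lists, in 43 of 49 clusters. Hepatocyte-like cells made up 38.8% of control cells, 37.1% of low-AFP cells, 40.5% of high-AFP cells and 6.20% of HCC cells, shares that the 1:1 mix and the sort set in part. It is unclear whether that mix was made for the HCC suspension, so its hepatocyte-like and immune shares may not be comparable with the others. The unnamed clusters 10, 22, 25 and 43, in which hepatocyte markers scored first or second, are outside these shares. They held 294, 0, 1 and 0 cells in control, 208, 0, 3 and 0 in low-AFP, 282, 19, 13 and 2 in high-AFP, and 90, 327, 282 and 54 in HCC, more there than the 461 named hepatocyte-like cells. Shares of the other types are therefore given within the named non-hepatocyte cells, with exact 95% binomial intervals that cover counting error only. Immune cells were 46.3% (44.6 to 48.0) of these in control, 68.9% (67.2 to 70.6) in low-AFP, 67.8% (66.4 to 69.2) in high-AFP and 97.0% (96.5 to 97.4) in HCC. Endothelial-like cells were 48.5% (46.8 to 50.2) in control, 28.6% (27.0 to 30.2) in low-AFP, 30.2% (28.9 to 31.6) in high-AFP and 1.67% (1.36 to 2.02) in HCC. Immune and endothelial-like cells made up most of the same total, so the opposite directions of their shares are not independent results. Macrophage-like cells were 13.9% (12.8 to 15.1), 21.1% (19.7 to 22.6), 25.8% (24.5 to 27.1) and 3.38% (2.94 to 3.87) in control, low-AFP, high-AFP and HCC, from 465, 635, 1126 and 203 cells. The unnamed cluster 13, with C1qa, C1qb and C1qc among its leading genes, held a further 113, 127, 286 and 203 cells, so these shares depend on leaving it out, most of all in HCC. Monocyte-like cells were 2.78% (2.25 to 3.40), 11.6% (10.5 to 12.8), 10.3% (9.44 to 11.3) and 19.9% (18.9 to 20.9). T-like cells were 10.6% (9.59 to 11.7), 13.1% (12 to 14.4), 11.2% (10.3 to 12.2) and 41.4% (40.2 to 42.7). Among immune cells alone, the T-like share was 22.9% (20.8 to 25.1) in control, 19.1% (17.4 to 20.8) in low-AFP, 16.6% (15.3 to 18) in high-AFP and 42.7% (41.4 to 44.0) in HCC. B-like cells were 6.07%, 8.99%, 7.22% and 11.9% of the non-hepatocyte cells, and conventional dendritic-like cells 4.34%, 7.39%, 7.65% and 10.2%. The largest dendritic-like cluster, 14, scored almost as high for monocyte markers. Neutrophil-like cells were 1.41%, 1.90%, 1.35% and 3.68%, NK-like cells 3.71%, 2.16%, 2.54% and 4.16%, and mesenchymal-like cells 2.87%, 0.166%, 0.160% and 0.0666%, the last from 96, 5, 7 and 4 cells. Of the 124 control NK-like cells 92 lay in cluster 39, which scored almost as high for T cell markers. The other NK-like cluster, 17, held 32, 58, 104 and 250 cells. The control NK-like share is therefore not comparable with the others, and the control T-like share depends on leaving cluster 39 out. The unnamed cluster 40, with mesenchymal genes such as Dcn and Col3a1 in front and mesothelial markers scoring first, held 37, 9, 14 and 11 cells. Unnamed clusters held 7.19% (6.56 to 7.86) of control cells, 6.51% (5.86 to 7.21) of low-AFP cells, 7.36% (6.81 to 7.94) of high-AFP cells and 13% (12.3 to 13.8) of HCC cells.

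**Figure D1:**
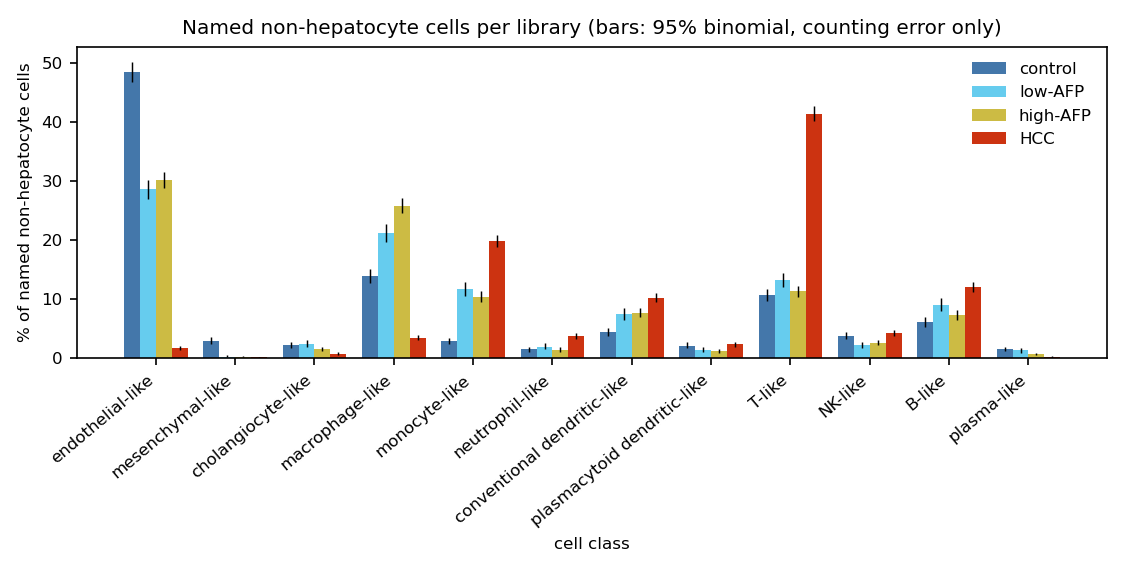
Share of named non-hepatocyte cells (percent) in each cell class for the 4 libraries, with exact 95% binomial bars that cover counting error only. Endothelial-like cells were 48.5% in control and 1.67% in HCC, and T-like cells 10.6% and 41.4%.

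Several classes were held by different clusters in different libraries, and with 1 library per group such a cluster can stand for a library as well as for a cell state. Cluster 0 held 64.8% of control hepatocyte-like cells, cluster 2 held 35.6% of low-AFP and 29.4% of high-AFP hepatocyte-like cells, and cluster 4 held 57.0% of those in HCC. T-like cells lay mostly in cluster 6 in control, in clusters 6 and 18 in low-AFP and high-AFP, and in clusters 7 and 12 in HCC. Endothelial-like cells lay mostly in cluster 1 in control (78.0%), in clusters 1 and 15 in low-AFP and high-AFP, and in clusters 28 (41.0%) and 45 (31%) in HCC. Macrophage-like cells lay mostly in cluster 9 in control (65.4%) and most often in cluster 11 in low-AFP (38.7%), high-AFP (40.6%) and HCC (43.3%). Genes that lead one of these clusters (Clec4f and Vsig4 in cluster 9, Gpnmb and Trem2 in cluster 11, Gsta1, Cbr3 and Gstm3 in cluster 19) differ between classes partly through which cluster the cells were in. In cluster 16, a hepatocyte-like cluster, the leading genes Chka, Neat1 and Gdf15 included stress-response genes.

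Afp encodes alpha-fetoprotein, a fetal liver protein that hepatocellular carcinoma can produce again. Its level (ENSMUSG00000054932) in hepatocyte-like cells was 0.676 counts per 1000000 nuclear-encoded UMIs (CPM) in control, with an exact 95% Poisson interval of 0.407 to 1.06 from 19 UMIs. It was 1.94 CPM (1.52 to 2.45, 71 UMIs) in low-AFP, 2.98 CPM (2.51 to 3.53, 137 UMIs) in high-AFP and 113 CPM (102 to 125, 389 UMIs) in HCC. T-like cells, which should lack Afp, had 3.96 CPM (1.45 to 8.62) in control, 2.73 CPM (0.888 to 6.38) in low-AFP, 3.64 CPM (1.46 to 7.49) in high-AFP and 5.04 CPM (3.83 to 6.51) in HCC. Other classes differed from this: in high-AFP, endothelial-like cells had 0.165 CPM (0.00419 to 0.922), monocyte-like cells 0 UMIs (up to 1.14 CPM) and macrophage-like cells 1.87 CPM (1.17 to 2.83). In low-AFP, conventional dendritic-like cells had 0 UMIs (up to 1.26 CPM), endothelial-like cells 0.739 CPM (0.152 to 2.16) and macrophage-like cells 2.25 CPM (1.29 to 3.65). By these intervals the low-AFP and high-AFP levels of the whole hepatocyte-like class were above some other classes and not above others. How far the class as a whole exceeds background stays open. Hepatocyte-like cluster 19, with 288 high-AFP cells, had 33.6 CPM there (25.1 to 43.9) from 53 UMIs in 26 cells, at most 16 in 1 cell. That interval lay above those of the T-like, macrophage-like, endothelial-like and monocyte-like cells of high-AFP. Cluster 2 had 0.888 CPM (0.550 to 1.36) in high-AFP. In low-AFP, cluster 19 held 42 of the 71 UMIs, 32 of them in 1 cell. The HCC level was above those of T-like, macrophage-like, monocyte-like and endothelial-like cells of its library, and its interval overlapped that of cholangiocyte-like cells (81.8 CPM, 60.9 to 108). Single cells weighed heavily: 1 low-AFP cell held 32 of the 71 Afp UMIs, and without the top cell of each library the levels were 0.606, 1.07, 2.24 and 96.8 CPM, with the intervals of control (0.353 to 0.970) and low-AFP (0.760 to 1.46) overlapping. In HCC, cluster 46, with 20 cells and 20.8% of the UMIs of the hepatocyte-like class, had Afp at 475 CPM (424 to 530), and without it the HCC level was 26.7 CPM. Over the alternative settings, the HCC level lay between 3.16 CPM, in cells of cluster 4 alone, and 266 CPM, with a mitochondrial limit of 15%. The levels of the others lay between 0 and 1.55 CPM in control, 0 and 4.33 CPM in low-AFP, and 1.5 and 7.39 CPM in high-AFP, while the Afp CPM of other classes was not taken under these settings. The share of hepatocyte-like cells with an Afp UMI was 0.708% (0.413 to 1.13), 1.37% (0.901 to 1.98), 2.03% (1.59 to 2.57) and 11.9% (9.12 to 15.2) in control, low-AFP, high-AFP and HCC, at median depths of 14391, 18634.5, 13784.5 and 3106 UMIs. In T-like cells the share was 1.41%, 1.27%, 1.43% and 2.21% at median depths of 4050, 4207, 3477 and 4234 UMIs. With each cell thinned to 1000 UMIs, 0 of 2373 control hepatocyte-like cells had an Afp UMI, which allows up to 0.155% of cells to be detected at this depth and does not limit expression, since 17 of all control cells of the class had an Afp UMI before thinning. The thinned shares were 0.155% (0.0321 to 0.453) in low-AFP, 0.487% (0.278 to 0.789) in high-AFP and 4.11% (2.41 to 6.49) in HCC, against 0.284%, 0.260%, 0.205% and 0.449% in the thinned T-like cells of control, low-AFP, high-AFP and HCC. The T-like share in high-AFP rests on 1 of 487 cells (0.00520 to 1.14), beside 0 of 1310 endothelial-like cells (up to 0.281%), 0 of 451 monocyte-like cells (up to 0.815%) and 2 of 1119 macrophage-like cells (0.179%, 0.0217 to 0.644) there. Thinned B-like cells had higher shares than hepatocyte-like cells in low-AFP (0.746%, 2 of 268 cells, 0.0905 to 2.67) and high-AFP (0.974%, 3 of 308 cells, 0.201 to 2.82). Their shares were 0% in control and 0.141% in HCC. At equal depth the high-AFP hepatocyte-like interval overlapped that of each of these high-AFP classes. The HCC hepatocyte-like interval lay above that of the T-like cells of HCC.

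**Figure D2:**
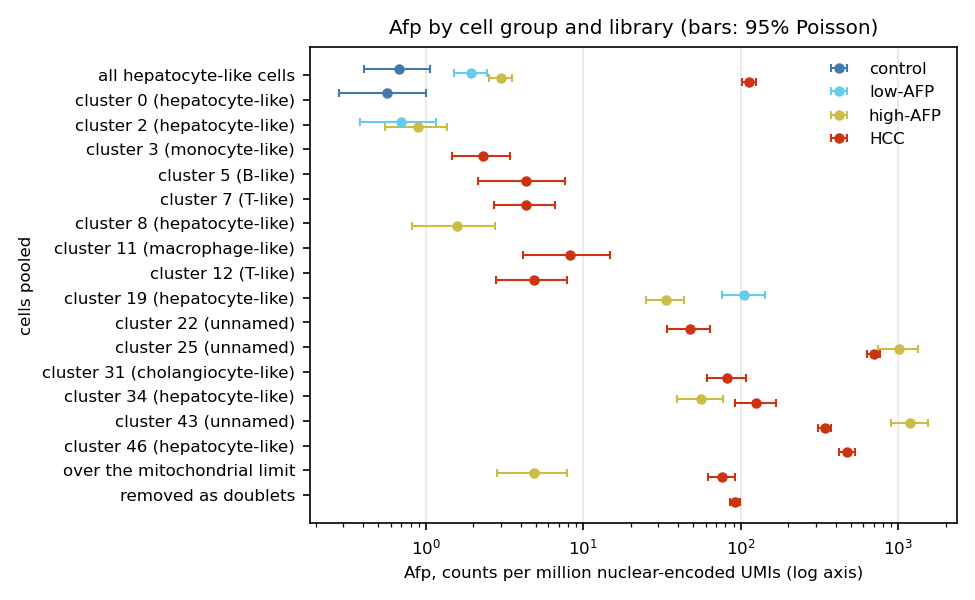
Afp level (CPM, log axis) by cell group or cluster in the 4 libraries, with exact 95% Poisson bars that cover counting error only. Hepatocyte-like cells had 0.676 CPM in control and 113 CPM in HCC.

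Log2 folds below are log2 of the ratio of class CPM values after adding 10 CPM to each. Genes called most higher or most lower are those taken by the naming rule, so genes outside it, given under their lists, can have larger folds. List medians are set against 10000 random lists of the same size matched on expression: a list is called higher or lower when its median lies above or below the central 95% of these, as a description of the libraries compared. Near-identical paralogs (the Mup, Cyp2c, Cyp2a4 and Cyp2a5, Gsta1 and Gsta2, Saa1 and Saa2, and Serpina3 genes) share reads, so which family member a value belongs to is uncertain.

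In the low-AFP library, hepatocyte-like cells had lower transcripts of fat synthesis and higher transcripts of glutathione conjugation and carcinoma-associated genes than in control. Of 334 measured genes on the fixed hepatocyte lists, 33 were at least 2-fold higher and 16 at least 2-fold lower. Among the genes taken by the naming rule, the largest higher folds were for Gsta1, a glutathione S-transferase (131 against 5.23 CPM, log2 3.21), Lcn2, an iron-binding acute phase protein (257 against 36.3 CPM, 2.53), and Serpina7, thyroxine-binding globulin (146 against 21.1 CPM, 2.33). Ccnd1, cyclin D1 (144 against 21.9 CPM, 2.27), and Cdkn1a, the cell cycle inhibitor p21 (85.2 against 15.8 CPM, 1.88), were both higher. Gstm3 (2.24), Lgals1, galectin-1 (2.15), Rad51b (2.14), Ntrk2 (1.71), Ifi27l2b (1.68), Cyp2a5 (1.62) and Saa2 (1.55) completed the 12 genes most higher. The gene most lower was Slco1a1, an organic anion transporter (4.87 against 76.7 CPM, -2.54), followed by Fabp5 (-2.03), Cyp2c37 (-1.77), Sult2a8 (-1.73) and Cyp2c54 (-1.69). Slc10a1, the sodium-dependent bile acid uptake transporter (439.5 against 1079.8 CPM, -1.28), Ces3b (-1.27) and Cyp2u1 (-1.24) were also among the 12 most lower.

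Of 14 measured de novo lipogenesis genes in this comparison, 7 were at least 2-fold lower and 0 higher, with a median log2 fold of -0.96 (percentile 0). They included Scd1, stearoyl-CoA desaturase (5166 against 16644 CPM, -1.69), Acss2 (48.5 against 150.1 CPM, -1.45), Thrsp (-1.37), Acacb (-1.32), Acly (-1.17) and Fasn, fatty acid synthase (434 against 887 CPM, -1.02). Lipid droplet and fatty acid uptake genes went the other way, with 4 of 12 higher and 0 lower (median 0.38, percentile 99.96): Cidec, a lipid droplet fusion protein (24.1 against 2.14 CPM, 1.49), Fitm1 (1.32), the fatty acid transporter Cd36 (1.15) and Fabp4 (1.11). The PPAR alpha and fatty acid oxidation list had a higher median (0.29, percentile 99.8), with 1 of 20 at least 2-fold higher, Cyp4a10 (626 against 258 CPM, 1.25). Lower medians were found for cholesterol synthesis (-0.25 over 18 genes), bile acid synthesis and transport (-0.34 over 15), urea cycle and amino acid breakdown (-0.31 over 14), periportal hepatocyte genes (-0.40 over 14) and male-biased liver genes (-0.53 over 13), each at percentile 0. The oncofetal and carcinoma list had 9 of 12 measured genes higher and 0 lower (median 1.60, percentile 100), led by Ly6d (202 against 7.51 CPM, 3.6), Spp1, osteopontin (295 against 27.9 CPM, 3.01), Anxa2, annexin A2 (2.33), and S100a11 (2.17). In the acute phase list 6 of 21 were higher and 0 lower, among them Lcn2, Saa2, Orm2 (1.55) and Saa1 (1.49), while the list median of 0.22 was inside the range of random lists. The NRF2 and glutathione list was higher (median 0.66, percentile 100, 3 of 19 at least 2-fold higher), as was the interferon list (median 0.46, percentile 100, 0 of 17 at least 2-fold higher). MHC class II transcripts, which belong mainly to immune cells, were higher in 4 of 4 (median 1.08), with Cd74 at 78.6 against 15.6 CPM (1.79). Immune transcripts in these droplets moved with them: 1 of 3 measured was higher (median 0.72, percentile 99.8). Transcripts of other non-parenchymal cells were lower (median -0.60 over 3 genes, percentile 0.11).

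Compared with control, the high-AFP library had hepatocyte-like cells with higher glutathione transferase and carcinoma-associated transcripts and lower albumin. Of 335 measured fixed-list genes, 41 were at least 2-fold higher and 18 at least 2-fold lower, the latter 65 when cells of cluster 4 alone were compared. Gsta1 was at 282 against 5.23 CPM (4.26), Gstm3 at 190.0 against 9.36 CPM (3.37) and Cbr3, a carbonyl reductase (ENSMUSG00000022947), at 93.4 against 0.142 CPM (3.35), the last from 4287 against 4 UMIs. Cyp2a5 (231 against 29.7 CPM, 2.60), Ubd, a ubiquitin-like modifier (54.4 against 0.854 CPM, 2.57), Cyp2a4 (2.25), Lgals1 (2.20), Cib3 (2.14), Ntrk2 (2.13), Serpina7 (1.99), Gsta2 (1.91) and Cstb (1.82) were the next most higher. Alb, albumin (ENSMUSG00000029368), was at 19703 against 64883 CPM (-1.72), and Slc10a1 at 327 against 1079.8 CPM (-1.69). The others among the 12 most lower were Cyp2c37 (-1.94), Chka (-1.60), Rgs16 (-1.46), Fos (-1.43), Serpina3k (-1.40), Slco1a1 (-1.36), Apoa4 (-1.34), Cyp17a1 (-1.31), Retsat (-1.28) and Igfbp1 (-1.28).

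The NRF2 and glutathione list had 9 of 19 genes at least 2-fold higher in high-AFP than in control and 0 lower (median 0.74, percentile 100), among them Srxn1, sulfiredoxin (1.65), Gstm1 (1.55) and Gsta4 (1.52). The oncofetal and carcinoma list had 8 of 11 higher and 0 lower (median 2.18, percentile 100): Spp1 (ENSMUSG00000029304) was at 632 against 27.9 CPM (4.08), Ly6d at 212 against 7.51 CPM (3.66) and S100a11 at 2.45. In de novo lipogenesis 1 of 14 genes, Elovl6 (96.8 against 225 CPM, -1.14), was at least 2-fold lower, while the list median was -0.76 (percentile 0), with Scd1 (ENSMUSG00000037071) at 8859 against 16644 CPM (-0.91). Lipid droplet genes were higher (median 0.32, percentile 98.7), with Fitm1 (1.79), Cidec (1.71) and Fabp4 (1.34). The median of complement and coagulation genes was lower (-0.49 over 23 genes, percentile 0), as were those of drug-metabolising cytochrome P450 genes (-0.36 over 17, percentile 0), cholesterol synthesis (-0.24 over 18, percentile 0), periportal genes (-0.20 over 14, percentile 1.01, but 0.057 in cells of cluster 4 alone) and female-biased liver genes (-0.79 over 4, percentile 0). Unfolded protein and integrated stress response genes were lower too (-0.33 over 14, percentile 0.02). Dissociation and immediate early genes were lower in high-AFP (median -0.44 over 17, percentile 0), including Egr1 (-1.01), while the small heat shock gene Hspb1 was higher (1.80). Interferon genes were higher (median 0.54, percentile 100), with Cxcl9 (67.8 against 23.3 CPM, 1.22) and Psmb9 (1.04). The acute phase median of 0.12 was inside the range of random lists, with 6 of 21 genes higher, led by Lcn2 (1.64) and Saa2 (1.44). MHC class II transcripts were higher in 4 of 5 (median 1.13, percentile 100), with Cd74 at 89.2 against 15.6 CPM (1.96), beside immune transcripts that were higher in 2 of 6 (median 0.89, percentile 99.98). The blood transcript Hbb-bs was at 20.7 against 1.03 CPM (log2 1.48), and trimmed-mean scaling would shift all folds of this comparison by -0.12.

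Set directly against each other, the low-AFP and high-AFP hepatocyte-like cells differed in fewer fixed-list genes than either did from control. Of 337 measured, 6 were at least 2-fold higher in high-AFP and 6 at least 2-fold lower, against 10 and 26 when cells of cluster 4 alone were compared. Afp itself was 2.98 against 1.94 CPM, and without the top cell of each library 2.24 against 1.07 CPM. Cyp4a10 and Cyp4a14, omega-hydroxylases of fatty acids and targets of PPAR alpha, were lower in high-AFP (112 against 626 CPM, -2.38, and 95.7 against 417 CPM, -2.01), and the PPAR alpha and fatty acid oxidation list was lower as a whole (median -0.24, percentile 0, 2 of 20 at least 2-fold lower). The major urinary protein gene Mup21 was at 769 against 182 CPM (2.02) and Mup20 at 40170.0 against 23322 CPM. The male-biased liver genes had a higher median (0.53, percentile 100, 2 of 14 at least 2-fold higher) and the female-biased genes a lower median (-0.61 over 4 genes, percentile 0), including Cyp2b9 (-1.36). Cbr3 (93.4 against 23.1 CPM, 1.64), Sult2a8 (1.34), Upp2 (1.13), Gstm3 (1.13), Alas1, the first enzyme of haem synthesis (1.11), Gsta1 (1.05), Cyp2a5 (0.99), Oat (0.97), Inmt (0.95) and Gadd45g (0.93) were higher. Chka, choline kinase alpha (107 against 394 CPM, -1.78), Cdkn1a (33.2 against 85.2 CPM, -1.14), Atf3 (-1.11), Apoa4 (-1.06), Ccnd1 (65.1 against 144 CPM, -1.03), Osgin1 (-0.94), Retsat (-0.91), Alb (-0.90), Lcn2 (-0.89) and Fos (-0.88) were lower. Spp1 was higher (1.07), while the oncofetal and carcinoma list median of 0.06 was inside the range of random lists, with 2 of 12 at least 2-fold higher. NRF2 and glutathione genes were higher (median 0.43, percentile 100). Acute phase genes (median -0.41 over 21), unfolded protein response genes (-0.58 over 14) and dissociation and immediate early genes (-0.39 over 17) were lower, each at percentile 0. The medians of de novo lipogenesis (0.16, percentile 99.7) and urea cycle genes (0.18, percentile 99.7) were higher, each with 0 genes past 2-fold. Immune transcripts in the hepatocyte-like droplets were higher by a median of 0.30 over 6 genes (percentile 100), and Hbb-bs was higher by 1.5. The male-biased median was -0.013 when cells of cluster 4 alone were compared, and the lipogenesis median was -0.0068 with a mitochondrial limit of 15%, so both directions depended on which cells were taken.

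HCC hepatocyte-like cells differed from control in more fixed-list genes than those of low-AFP or high-AFP did: of 363 measured, 108 were at least 2-fold higher and 100 at least 2-fold lower, and the former were 51 when cells of cluster 4 alone were compared. Pericentral, NRF2 and carcinoma-associated transcripts were higher, and periportal, lipogenic, complement and urea cycle transcripts lower. The class held 461 cells in HCC, against 2402 in control. Its median depth was 3106 against 14391 UMIs and its median mitochondrial share 3.67% against 22.1%. Cells matched on depth and mitochondrial share were not compared for HCC. Trimmed-mean scaling would shift all folds of this comparison by -0.42, and the median over all measured genes was 0.25. Ly6d was at 1205 against 7.51 CPM (6.12), Gsta1 at 575 against 5.23 CPM (5.26), Gstm3 at 637 against 9.36 CPM (5.06), Cyp2a5 at 979 against 29.7 CPM (4.64) and the stress-induced cofactor Nupr1 at 295 against 2.88 CPM (4.56). Anxa2 (4.54), Cbr3 (4.42), Cyp2a4 (4.42) and the chemokine gene Cxcl10 (245 against 6.51 CPM, 3.95) were also among the 12 most higher. The other 3 of these genes lead cluster 46, a cluster of 20 cells seen in HCC alone: Slc1a2, a glutamate transporter (1183 against 39.5 CPM, 4.59), Akr1c18 (228 against 0.0712 CPM from 785 against 2 UMIs, a ratio of 3208 with an interval of 885 to 26533), and the Wnt target Nkd1 (157 against 0.783 CPM, 3.95). Without cluster 46 the log2 folds of Slc1a2, Akr1c18 and Nkd1 were 2.54, 2.61 and 1.84. Lower genes were Slc10a1 (61.1 against 1079.8 CPM, -3.94), Serpina3k (-3.93), Cyp2f2 (68.4 against 1025 CPM, -3.72), Cps1, which starts the urea cycle (210.4 against 2509 CPM, -3.51), Etnppl (-3.27), Scd1 (1777 against 16644 CPM, -3.22), Hsd11b1 (-3.12), Cyp8b1 of bile acid synthesis (-3.12), Ctsc (-3.05), the glucose-6-phosphatase gene G6pc (79.1 against 706 CPM, -3.01), Ces3b (-2.93) and Elovl5 (-2.92).

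Zonation genes moved in opposite directions in the named hepatocyte-like cells of HCC against control. Of 16 pericentral genes, 14 were at least 2-fold higher and 1 lower (median 2.13, percentile 100), with Glul, glutamine synthetase (ENSMUSG00000026473), at 4105 against 307 CPM (3.70), Lect2 at 3.62, Cyp1a2 at 2.98 and the Wnt target Axin2 at 61.4 against 2.78 CPM (2.48). Of 14 periportal genes, 9 were lower and 0 higher (median -1.34, percentile 0), including Cyp2f2, Etnppl and Hal (68.4 against 531 CPM, -2.79). Without cluster 46 the pericentral median was 1.61 and the periportal median -1.21. The unnamed clusters 25 and 43, with 282 and 54 HCC cells, are outside this class, and their pericentral medians were lower than control. The oncofetal and carcinoma list had 15 of 17 genes higher and 2 lower (median 3.13, percentile 100), with Afp at 3.53, S100a11 at 4.14 and Lgals3 at 4.07, and with Sox9 (-1.68) and Mmd2 (-1.63) lower. Proliferation genes were higher in 16 of 19 (median 1.61, percentile 100), with Stmn1 (176 against 8.79 CPM, 3.31), Ube2c (78.8 against 1.57 CPM, 2.94) and Birc5 (2.65). Cluster 34, led by Cdca3, Cdc20, Cdkn3, Birc5 and Ube2c, held 58 of the 461 HCC hepatocyte-like cells and 10 of the 2402 in control. NRF2 and glutathione genes were higher in 13 of 19 (median 1.61, percentile 100), including Gstm2 (3.62) and Gsta2 (2.89). Glycolysis and hypoxia genes were higher in 5 of 13 (median 0.84, percentile 99.1), with Ndrg1 (2.35) and Pkm (1.93), and interferon genes in 8 of 19 (median 0.77, percentile 99.95), with Ifit2 (2.93) and Isg15 (2.33). Lower lists were de novo lipogenesis (10 of 14 lower, median -1.61), complement and coagulation (18 of 23 lower, median -1.35, with C8b at -2.19), acute phase (12 of 21 lower and 4 higher, median -1.08) and male-biased liver genes (8 of 13 lower, median -1.30, with Mup3 at -2.61), each at percentile 0. In the acute phase list Fga (-2.63), Hamp (-2.41) and Fgg (-2.22) were lower, while Lcn2 was higher (2.39). The urea cycle list (median -0.43, percentile 1.57), gluconeogenesis (-0.64, percentile 0.88), bile acid genes (-0.68, percentile 0.07), cholesterol synthesis (-0.46, percentile 0.05) and choline and one-carbon genes (-0.51, percentile 0.485) were lower as well, but in cells of cluster 4 alone the urea cycle median was 0.076 and the choline and one-carbon median 0.034. The stress genes Ddit3 (162 against 25.3 CPM, 2.28) and Trib3 (1.86) were higher, while the unfolded protein response list was lower (-0.32 over 15 genes, percentile 2.26), with Herpud1 at -2.00. The PPAR alpha list (median 0.50, 6 higher and 4 lower of 20), the p53 list (0.53) and dissociation and immediate early genes (0.51) lay inside the range of random lists. MHC class II transcripts were higher in 5 of 5 (median 2.15) and MHC class I transcripts had a median of 0.05 inside the range, with H2-K1 (-1.18) and B2m (-1.10) lower. Beside these, immune transcripts in the hepatocyte-like droplets were higher in 11 of 13 (median 1.82, percentile 100), such as S100a9 (68.7 against 1.25 CPM, 2.81), blood transcripts in 4 of 5 (median 1.73), and transcripts of other non-parenchymal cells were lower in 3 of 4 (median -1.17).

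Against the high-AFP library, HCC hepatocyte-like cells again had higher pericentral and proliferation transcripts and lower lipogenic, complement and male-biased transcripts. Of 364 measured fixed-list genes, 78 were at least 2-fold higher and 66 at least 2-fold lower, and 14 and 12 when cells of cluster 4 alone were compared. Afp was at 113 against 2.98 CPM (3.25), and at 1.5 without cluster 46. The genes most higher were largely those that lead cluster 46: Slc1a2 (1183 against 33.4 CPM, 4.78), Akr1c18 (228 against 1.13 CPM, 4.42), Nkd1 (3.98), Plat, tissue plasminogen activator (124 against 0.283 CPM, 3.70), Glul (4105 against 351 CPM, 3.51) and Cpe (3.22). Sfrp2 (466 against 0 UMIs, at least 2075-fold higher), Car4 (397 against 0 UMIs, at least 1768-fold) and Pnliprp1 (273 against 0 UMIs, at least 1216-fold) had no UMI in high-AFP hepatocyte-like cells. Without cluster 46 the log2 folds were 2.73 for Slc1a2, 2.47 for Akr1c18, 1.86 for Nkd1, 2.01 for Plat, 2.83 for Glul, 0.20 for Cpe, 0.05 for Sfrp2 and Car4, and 0.10 for Pnliprp1. Nupr1 (295 against 13.4 CPM, 3.70) and Igfbp1 (809 against 85.8 CPM, 3.10, and 1.23 without cluster 46) were also among the most higher. The hepcidin genes Hamp2 (55.3 against 596 CPM, -3.21) and Hamp (401 against 2987 CPM, -2.87), Mup21 (74.8 against 769 CPM, -3.20), Cps1 (-3.13), Cyp2f2 (-2.98), Pigr (-2.56), Apon (-2.56), Slc7a2 (-2.55), Serpina3k (-2.53), Mup3 (-2.49), Noct (-2.45) and Ntrk2 (-2.43) were the most lower.

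In this comparison 14 of 16 pericentral genes were at least 2-fold higher (median 1.87, percentile 100, and 1.21 without cluster 46), including Lect2 (2.58), Axin2 (2.46) and Lhpp (2.41). Periportal genes were lower in 8 of 13 (median -1.37, percentile 0). The oncofetal and carcinoma list had 11 of 18 genes higher and 3 lower (median 1.57, percentile 100), with S100a6 (2.52), Lgals3 (2.52) and Gpc3, glypican-3 (33.2 against 0.218 CPM, 2.08), higher and Spp1 lower (66.6 against 632 CPM, -3.07). Proliferation genes were higher in 13 of 19 (median 1.31, percentile 100), with Ube2c (2.48) and Stmn1 (2.21). The NRF2 and glutathione list was higher (median 0.78, percentile 100), with Gstm2 (2.48) and Gstm3 (1.69), but its median was -0.18 when cells of cluster 4 alone were compared. De novo lipogenesis (median -0.92, 6 of 14 lower), acute phase (-0.77, 8 of 21 lower), complement and coagulation (-0.81, 10 of 23 lower) and male-biased genes (-1.25, 8 of 14 lower) were lower, each at percentile 0. Gluconeogenesis (-0.70, percentile 0.07), choline and one-carbon (-0.45, percentile 0.035) and urea cycle genes (-0.30, percentile 1.79) were lower, and the urea cycle median was 0.0029 without cluster 46, 0.094 with cells weighted equally and 0.26 with cells thinned to 1000 UMIs. Dissociation and immediate early genes were higher in 7 of 18 (median 0.80, percentile 100), with Atf3 (203 against 31.6 CPM, 2.36) and Ier3 (2.26), and at 0.49 without cluster 46. Glycolysis and hypoxia genes (median 0.75, percentile 99.9) and interferon genes (0.48, percentile 99.2, with Cxcl10 at 2.95) were higher. Immune transcripts in the hepatocyte-like droplets were higher in 8 of 13 (median 1.05, percentile 100, with S100a9 at 2.85), beside blood transcripts in 4 of 5 (median 1.36) and MHC class II transcripts in 2 of 5 (median 0.96). Trimmed-mean scaling would shift all folds of this comparison by -0.29, and the median over all measured genes was 0.17.

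**Figure D3:**
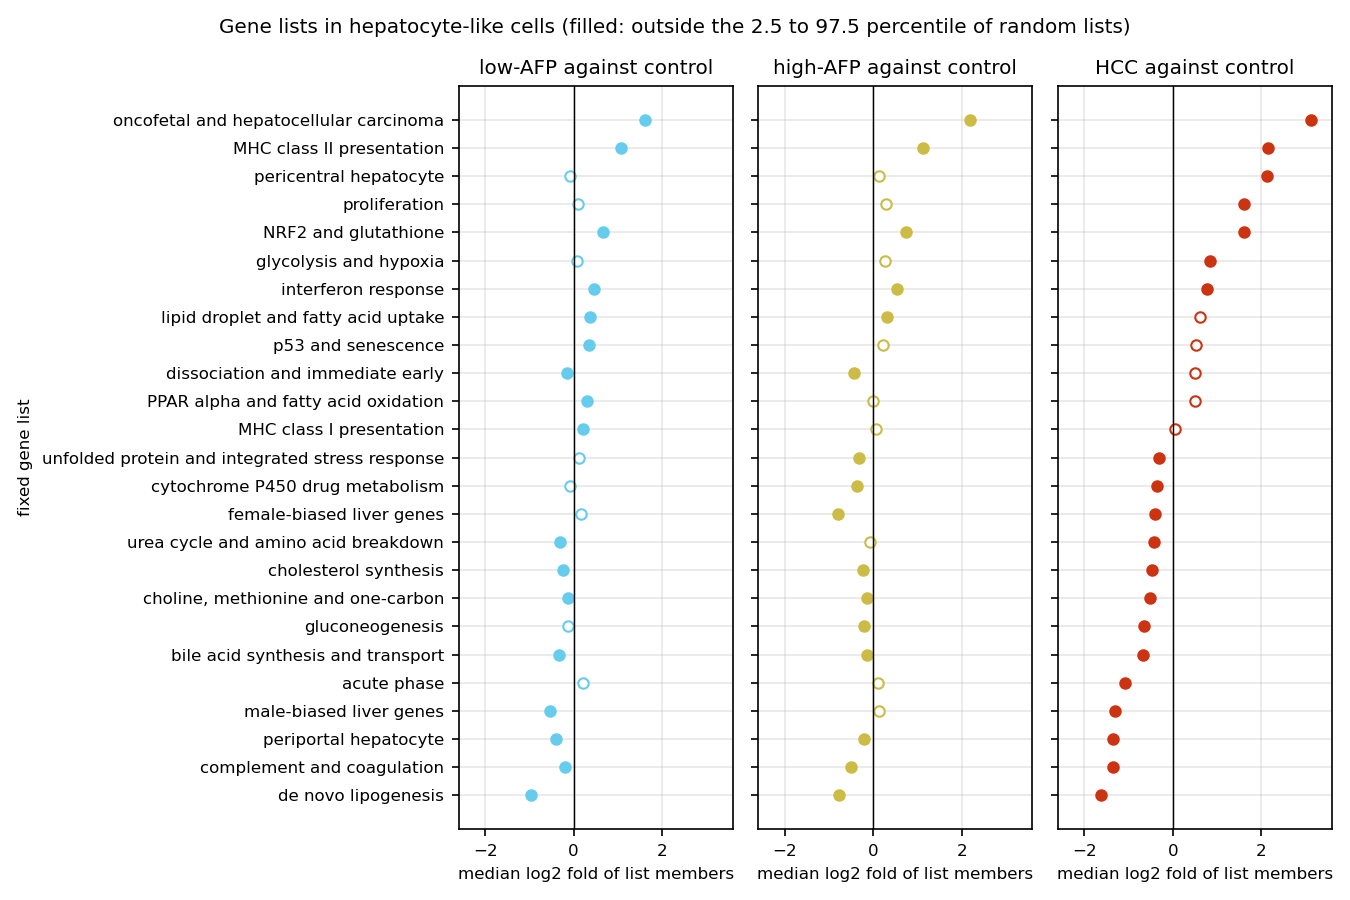
Median log2 fold of each fixed gene list in hepatocyte-like cells of the low-AFP, high-AFP and HCC libraries against control (1 panel each, log2 on the horizontal axis). Filled points lie outside the central 95% of random matched lists, as for de novo lipogenesis at -0.96, -0.76 and -1.61.

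Macrophage-like cells of the low-AFP, high-AFP and HCC libraries had lower Kupffer cell transcripts and higher lipid-associated macrophage transcripts than those of control. They lay mostly in clusters 9 and 11, and the rest in clusters 30, 32 and 36. Cluster 32 scored 1.815 for macrophage and 1.408 for endothelial markers. It held 37, 55, 131 and 1 cells in control, low-AFP, high-AFP and HCC. Cluster 36 scored 1.585 for macrophage and 1.253 for T cell markers. Whether such clusters account for values of this class was not tested. The Kupffer cell identity list had 7, 6 and 8 of 15 genes at least 2-fold lower in low-AFP, high-AFP and HCC (medians -0.96, -0.85 and -1.28, each at percentile 0). Cd163, a haemoglobin scavenger receptor, was at 233 CPM in control and at 2.95, 2.72 and 4.82 CPM in low-AFP, high-AFP and HCC (-4.23, -4.25 and -4.03). Marco, a scavenger receptor, was at 204 CPM in control, 12.5 CPM in low-AFP (-3.25) and 14.8 CPM in high-AFP (-3.11). In HCC, Marco had 1 UMI against 533 in control, a ratio of 591 with an interval of 106 to 23406. Timd4, a receptor of resident macrophages, was lower by log2 values of -1.87, -2.09 and -2.56, and Vsig4 by -1.07, -3.01 and -3.50. The lipid-associated list had 6 of 17, 6 of 18 and 8 of 18 genes higher (medians 0.64, 0.51 and 0.96, each at percentile 100). Gpnmb was at 66.9 CPM in control and 208, 249.6 and 557 CPM in low-AFP, high-AFP and HCC (1.5, 1.76 and 2.88), and Lgals3, galectin-3, at 519, 1185, 1267 and 2501 CPM (1.18, 1.27 and 2.25). Fabp5 was at 104, 252, 345 and 929 CPM (1.21, 1.64 and 3.05), and Trem2, a lipid-sensing receptor, had folds of 1.02, 1.07 and 1.01. Ccl9 (1.40) and Cd63 (1.14) were also most higher in low-AFP, Ccl8 (2.25) and Ctla2a (1.33) in high-AFP, and Ccl8 (2.99) and Atp6v0d2 (2.66) in HCC. The complement gene C6, on the Kupffer list, was lower in low-AFP (101 against 429 CPM). Transcripts of stromal, endothelial or plasma cells, such as Dcn (-2.26) in low-AFP, Jchain (-3.99) and Dcn (-2.36) in high-AFP and Ehd3 (-4.03), Jchain (-3.76) and Bmp2 (-3.75) in HCC, were among the most lower in this class. Cxcl13 was also among the most lower in low-AFP (-2.85), while low-AFP monocyte-like cells had 223 Cxcl13 UMIs against 0 in control. Between high-AFP and low-AFP both lists lay inside the range of random lists (Kupffer 0.07, lipid-associated 0.02). Against high-AFP, HCC macrophage-like cells had Kupffer genes at -0.28 (percentile 0) and lipid-associated genes at 0.43 (percentile 100).

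T-like cells had higher cytotoxicity and exhaustion transcripts in low-AFP, high-AFP and HCC than in control, where 91.0% lay in cluster 6. Cluster 39, with 92 control cells and 7, 7 and 0 in low-AFP, high-AFP and HCC, is outside this class. It was named NK-like, with scores of 1.61 for NK and 1.54 for T cell markers, and Gzma, Gzmb and Cd160 were among its leading genes. How far its absence lowers the control levels of such genes was not tested. The cytotoxicity list had 9, 8 and 9 of 14 genes at least 2-fold higher (medians 1.23, 1.15 and 1.46, each at percentile 100), and the exhaustion list had 6 of 13, 5 of 12 and 9 of 13 (medians 0.77, 0.75 and 1.73, each at percentile 100). The chemokine gene Ccl4 was at 55.4 CPM in control and 1596, 1511 and 2268 CPM in low-AFP, high-AFP and HCC (4.62, 4.54 and 5.12), and Ccl3 at 19.1, 514, 511 and 979 CPM. The granzyme gene Gzmk had folds of 2.00, 2.45 and 2.71. Pdcd1, which encodes the checkpoint receptor PD-1, was at 18.5 CPM in control and 143, 131 and 246 CPM (2.43, 2.31 and 3.17). Tox, a transcription factor of exhausted T cells, had folds of 1.21, 1.24 and 2.13. Lag3, another checkpoint receptor, was at 21.1 CPM in control, 229.7 CPM in low-AFP (2.95) and 176 CPM in high-AFP (2.58). Havcr2, encoding TIM-3, had 1 UMI in control T-like cells, and the high-AFP ratio was 107 with an interval of 18.9 to 4257. The opioid precursor gene Penk had 2 UMIs in control, with ratios of 47.6 (12.9 to 398) in low-AFP and 45.6 (12.4 to 381) in high-AFP, and Coch had 1 UMI in control and a ratio of 181 (32.1 to 7166) in low-AFP. In HCC, Nr4a2 (626 against 19.8 CPM, 4.42), Ier3 (381 against 15.2 CPM, 3.96) and Spp1 (138 against 5.94 CPM, 3.22) were the next most higher after Ccl4 and Ccl3. The genes most lower in the 3 libraries were Mmp9 (-2.52, -2.44 and -3.41), Atp8a2 (-2.22, -2.73 and -3.01), Rcbtb2 (-1.94, -1.97 and -2.57), Plac8 (-1.86 and -2.31 in low-AFP and high-AFP), Satb1 in low-AFP (-1.83), Itga1 in high-AFP (-2.32) and HCC (-2.97), and P2rx7 in HCC (-2.71). The naive and memory list was lower in low-AFP (-0.49, percentile 0.01) and high-AFP (-0.47, percentile 0.04) and inside the range in HCC (-0.26). Regulatory T cell genes were higher (medians 1.00, 0.50 and 0.58, each at percentile 100), with the costimulatory receptor gene Tnfrsf4 at 1.5 in low-AFP. In HCC, however, Foxp3 (11.2 against 18.5 CPM, -0.43), Il2ra (13.6 against 31.7 CPM, -0.82) and Tnfrsf18 (-0.36) were lower than in control, and Ctla4 (2.03) is on the exhaustion list as well. Against high-AFP, HCC T-like cells had a higher exhaustion median (0.70, percentile 100) and a lower proliferation median (-0.54, percentile 0). Dissociation and immediate early genes were higher in the same HCC T-like cells (median 0.59 against high-AFP and 0.64 against control, each at percentile 100), with Junb at 2.14, Dusp1 at 2.03 and Ier3 at 1.71 against high-AFP. High-AFP T-like cells had a slightly lower exhaustion median than low-AFP ones (-0.17, percentile 1.77).

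Endothelial-like cells had higher capillarisation and angiogenesis transcripts than control in the other 3 libraries and lower sinusoidal transcripts. The capillarisation list had 7 and 6 of 17 genes higher in low-AFP and high-AFP (medians 0.38 and 0.38, each at percentile 100) and 18 of 21 in HCC (median 2.28, percentile 100). The sinusoidal identity list had medians of -0.34 and -0.38 in low-AFP and high-AFP with 0 of 14 past 2-fold, and of -1.92 in HCC with 9 of 14 lower. The HCC class held 100 cells, mostly in clusters 28 and 45, against 1622 in control, mostly in cluster 1. Esm1, a tip cell marker, was at 60.3 CPM in control, 275 CPM in low-AFP (2.02) and 299.5 CPM in high-AFP (2.14). Cd34 had folds of 1.35, 1.77 and 3.28, and Selp, P-selectin, of 1.49, 1.82 and 3.10. In low-AFP, Lyz2 (2.21), Fmo2 (1.85), the von Willebrand factor gene Vwf (267 against 71.2 CPM, 1.77) and Cd63 (1.70) were most higher beside Esm1, and Jchain (-2.70), Dcn (-1.56), Vipr1 (-1.23), Hpgd (-1.17) and Dkk3 (-1.13) most lower. In high-AFP, Ccl5 (152 against 12.4 CPM), Sprr2b (2.73), Gda (2.25) and Cd63 (2.06) were most higher, and Jchain (-2.87), Cyp26b1, a retinoic acid hydroxylase (213 against 1191 CPM, -2.43), Vipr1 (-2.00), Dcn (-1.78) and Rgs5 (-1.69) most lower. In HCC, Igfbp3 (721 against 6.98 CPM, 5.43), Ccl5 (824 against 12.4 CPM, 5.22), Emp1 (349 against 1.55 CPM, 4.96), Fmo2 (4.81) and Cd200 (428 against 9.15 CPM, 4.52) were most higher. Cyp26b1 (-4.60), Hpgd (-4.33), Bmp2 (136 against 2061 CPM, -3.82), Aass (-3.81) and Fcgr2b, a sinusoidal Fc receptor (176 against 2488 CPM, -3.75), were most lower. MHC class II genes were higher in low-AFP (5 of 7, median 1.22) and high-AFP (4 of 7, median 1.14), each at percentile 100, and interferon genes were higher as well (medians 0.62 and 0.35), with Cxcl9 at 1.69 and 1.33. Lyz2, Ccl5 and the MHC class II genes are abundant in immune cells.

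**Figure D4:**
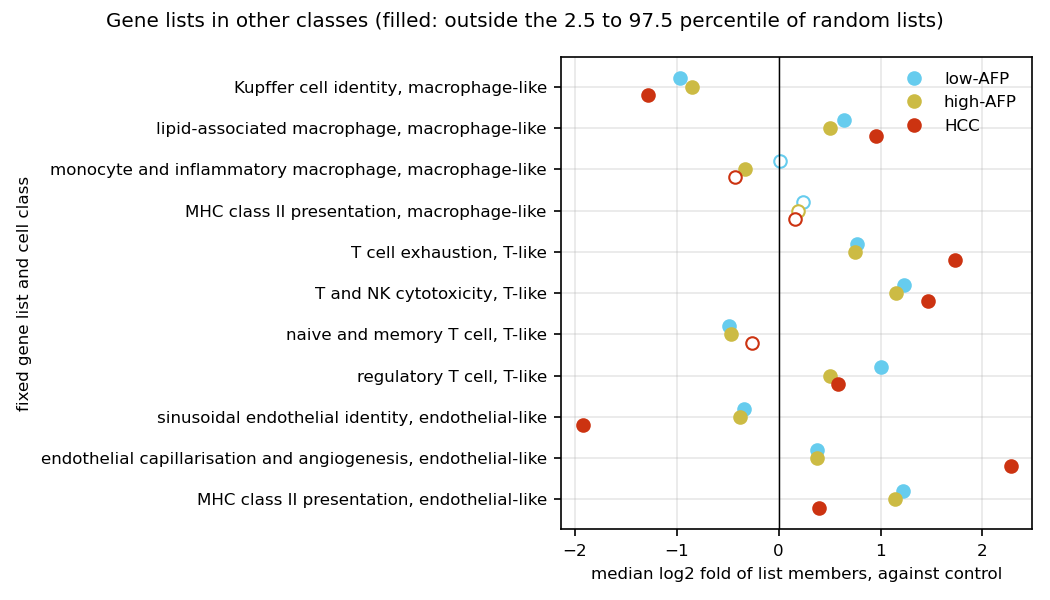
Median log2 fold of fixed gene lists in macrophage-like, T-like and endothelial-like cells of the low-AFP, high-AFP and HCC libraries against control (log2 on the horizontal axis). Filled points lie outside the central 95% of random matched lists, as for T cell exhaustion at 0.77, 0.75 and 1.73.

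Monocyte-like cells, mostly in cluster 3 in every library, had higher interferon transcripts in low-AFP and high-AFP than in control (medians 0.54 and 0.32 over 22 genes, each at percentile 100), and a median inside the range of random lists in HCC (0.03). Ifit2 (2.16) and Ifit3 (1.79) were among the genes most higher in low-AFP. Saa3, a serum amyloid gene, had 2 UMIs in control monocyte-like cells and ratios of 183 (50.7 to 1515) in low-AFP, 126 (34.7 to 1038) in high-AFP and 86.6 (23.9 to 715) in HCC. Retnla had 291 UMIs in control and 0 in each of the other 3 libraries, at least 453-fold lower in low-AFP. Fcna (-2.67, -3.28 and -3.41) was lower in low-AFP, high-AFP and HCC, and Lyve1 (-2.49 and -2.98) in low-AFP and high-AFP, with 0 UMIs in HCC against 57 in control (at least 336-fold lower). Fcna leads the macrophage-like cluster 9 and Lyve1 the endothelial-like cluster 15, and the control class held 93 cells. In HCC monocyte-like cells the immediate early genes Atf3 (2.20) and Fosb (1.56), the heat shock gene Hspa1a (2.12) and Socs3 (1.84) were higher. Conventional dendritic-like cells had higher interferon medians in low-AFP (0.30), high-AFP (0.41) and HCC (0.43), each at percentile 100, and Ifitm1 was higher by 2.54, 2.5 and 3.35. Ifitm1 is a leading gene of cluster 14, which held 38.6%, 48.2%, 49.1% and 60.3% of this class in control, low-AFP, high-AFP and HCC. Monocyte markers scored almost as high as dendritic ones in cluster 14 (0.932 against 1.09) and in cluster 44 (1.05 against 1.15). Whether monocytes in this class account for its values was not tested. In B-like cells the interferon list was higher in high-AFP (median 0.54, percentile 100), and Jchain, the joining chain of secreted antibodies, had 2 UMIs in low-AFP and 1 in high-AFP against 286 in control, ratios of 196 (53.6 to 1622) and 352 (62.8 to 13969), and a log2 fold of -4.48 in HCC. Jchain leads the plasma cell cluster 37 and was lower in macrophage-like and endothelial-like cells as well, and plasma-like cells were 1.44%, 1.23%, 0.596% and 0.0999% of the non-hepatocyte cells, from 48, 37, 26 and 6 cells. Neutrophil-like cells reached 50 cells in low-AFP, high-AFP and HCC, and the maturation and activation list was higher in HCC than in high-AFP (6 of 14 higher, median 0.57, percentile 98.2), with Cxcl2 (2.07), Ptgs2 (1.74) and Il1b (1.13). In the same comparison their dissociation and immediate early genes were higher (13 of 19, median 1.39, percentile 100).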

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

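The tests of RNA of cholangiocytes, of free RNA or doublets with HCC-type cells, of a shift of the scaling and of handling were chosen after their results were seen, and the other tests before. In 5 cases Afp in barcodes that no comparison used was above that in the control barcodes left out for the same reason, with intervals that did not overlap. It was higher with overlapping intervals in 3 more: 12.9 CPM in high-AFP barcodes removed as doublets, and 1.84 CPM and 2.42 CPM in low-AFP barcodes over the mitochondrial limit and in low-AFP unnamed clusters. In the unnamed clusters Afp was at 126 CPM (103 to 152) in high-AFP and 299 CPM (281 to 318) in HCC, against 1.91 CPM in control. The control cells lay in other clusters: 294, 113 and 37 of 445 in clusters 10, 13 and 40, and 0, 1 and 0 in clusters 22, 25 and 43. Since Afp is a leading gene of clusters 25 and 43, this contrast with control compares unlike cells. In barcodes over the mitochondrial limit it was at 4.90 CPM (2.85 to 7.84) in high-AFP and 75.9 CPM (61.9 to 92.1) in HCC, against 0.491 CPM in control. In barcodes removed as doublets it was at 91.9 CPM (85.0 to 99.3) in HCC, against 1.89 CPM in control.

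Of the 109 Afp UMIs in unnamed high-AFP cells, 50 lay in the 13 cells of cluster 25 and 56 in the 2 cells of cluster 43 (42 in 1 cell), 2 clusters that, like cluster 22 with 19 high-AFP cells, held mostly HCC cells. Barcodes swapped from the HCC library are argued against: 0 of the 34 high-AFP barcodes in these 3 clusters were also HCC barcodes. Free RNA or doublets with HCC-type cells stay open. The 13 high-AFP cells of cluster 25 had 1.44 times the Afp CPM of its HCC cells (lower bound 1.07), and 0.990 times without the 1 cell that held 22 of the 50 UMIs, but Afp is a leading gene of this cluster, so cells were placed there partly by Afp and the ratio cannot tell. Whether the high-AFP liver held a tumour, or tissue from 1 animal entered both libraries, was not tested.

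Higher oncofetal and carcinoma transcripts in the hepatocyte-like cells of low-AFP and high-AFP than in those of control came with higher immune transcripts in the same droplets. RNA of immune cells in the hepatocyte-like droplets would need a median of 4.34% of another class's level for the 9 higher genes in low-AFP. For the 8 in high-AFP it would need 4.22%. The fixed immune transcripts needed at most 0.313% and 0.488%, and all 9 and all 8 genes lay above those. The smallest were S100a6 at 0.393% in low-AFP, close to its limit, and Lgals3 at 0.987% in high-AFP. Counting intervals were not taken for these shares. A difference in mitochondrial share and depth between the hepatocyte-like cells is argued against as well: in matched cells the list medians were 1.72 in low-AFP and 1.93 in high-AFP, against 1.60 and 2.18 unmatched. RNA of cholangiocytes in the hepatocyte-like droplets is argued against too: the same genes would need a median of 8.68% of the cholangiocyte-like level in low-AFP and 24.5% in high-AFP (smallest 1.02% and 2.22%, for Spp1), while the fixed cholangiocyte markers outside the list, Krt7 and Cldn7, allow at most 0.167% and 0.0921%. Differences between animals stay open, as does the difference in diet or AFP label that the groups name, which was not tested with 1 library per group.

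Dissociation and immediate early genes were higher in HCC than in high-AFP in each of the 9 classes compared. A shift of the scaling between the 2 libraries is argued against, since the list median exceeded the median of all measured genes by at least 0.37, the smallest excess, in macrophage-like cells. Handling of the HCC library cannot be told apart from the tumour region, because both belong to the same library: the list lay above the central 95% of random lists in 9 of 9 classes against high-AFP and in 7 of 9 against control, where plasmacytoid dendritic-like cells took the place of neutrophil-like cells. The tumour region itself stays open as an untested biological explanation.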

How the results depend on the processing

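The settings that add unnamed hepatocyte-marker clusters, use the expected doublet rate everywhere, take cluster 4 alone or leave out cluster 46 were chosen after seeing the data. All 120 named gene folds kept their direction under each setting run. These genes were chosen for large folds in the same counts, so a reversal was unlikely. Their size did change, and several folds nearly vanished without cluster 46. Called hepatocyte-like list medians kept theirs in 95 of 95 with TMM scaling, doublets kept, both other Leiden resolutions and both other pseudocounts, in 92 of 92 with CPM over all UMIs, in 88 of 92 with a mitochondrial limit of 15% and in 82 of 90 in cluster 4 alone. Of the main values, 237 stayed the same and 59 moved, as follows, and the cause was not tested. The same means inside the 95% counting interval of the main value for a share or Afp level, and within 1.5 times the main count for a count of genes. Below, genes higher or lower means fixed-list genes at least 2-fold so in hepatocyte-like cells, and Afp means its CPM there.

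With a mitochondrial limit of 15%, Afp was 1.55 in control, 3.98 in low-AFP, 7.15 in high-AFP and 266 in HCC, the T-like share of immune cells in control 25.8%, and genes lower 30 for high-AFP with control and 10 for high-AFP with low-AFP. Reversed medians were -0.0068 for lipogenesis and -0.0082 for interferon (high-AFP with low-AFP), 0.14 for complement (low-AFP with control) and 0.28 for female-biased genes (HCC with control). With no limit, the immune share in control was 44.5%, the T-like share in high-AFP 15.0% and HCC Afp 131. With at least 1000 UMIs, Afp was 4.03 in high-AFP and 177 in HCC. With doublets kept, immune shares were 48.8% in control and 96.1% in HCC, the HCC T-like share 40.7%, and Afp 4.14 in high-AFP and 215 in HCC. With the expected doublet rate everywhere, T-like shares were 27.3%, 20.9% and 18.8% in control, low-AFP and high-AFP, the HCC immune share 92.2%, and Afp 4.12 in high-AFP and 212 in HCC. With unnamed clusters added, Afp was 5.25 in high-AFP and 212 in HCC, and the female-biased median (HCC with control) reversed to 0.27.

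With CPM over all UMIs, HCC Afp was 101. With cells weighted equally, Afp was 4.33, 6.22 and 52.1 in low-AFP, high-AFP and HCC, genes lower were 32 for high-AFP with control, genes higher 11 for high-AFP with low-AFP, and for HCC with high-AFP 50 were higher and 112 lower, with the urea cycle median reversed to 0.094. With cells thinned to 1000 UMIs, Afp was 0 in control, 7.39 in high-AFP and 59.3 in HCC, genes lower were 41 for high-AFP with control, genes higher 13 for high-AFP with low-AFP, and for HCC with high-AFP 49 were higher and 115 lower, with the urea cycle median reversed to 0.26. Thinning kept 2373, 1931, 3288 and 414 hepatocyte-like cells.

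In cluster 4 alone, Afp was 0 in low-AFP, 1.5 in high-AFP and 3.16 in HCC. Genes lower were 65 for high-AFP with control, genes higher and lower 10 and 26 for high-AFP with low-AFP and 14 and 12 for HCC with high-AFP, and genes higher 51 for HCC with control. Reversed medians there were 0.13 for gluconeogenesis, 0.22 for choline and one-carbon and 0.057 for periportal genes (high-AFP with control), -0.013 for male-biased and -0.0070 for interferon genes (high-AFP with low-AFP), 0.076 for urea cycle and 0.034 for choline and one-carbon genes (HCC with control), and -0.18 for NRF2 (HCC with high-AFP). Without cluster 46, HCC Afp was 26.7 and the urea cycle median (HCC with high-AFP) reversed to 0.0029. With a pseudocount of 1 CPM, genes lower were 10 for high-AFP with low-AFP. With 50 CPM, genes higher and lower were 15 and 9 for low-AFP with control, 22 and 4 for high-AFP with control and 1 and 3 for high-AFP with low-AFP, and genes higher 66 for HCC with control and 36 for HCC with high-AFP, since a larger pseudocount shrinks folds. With a minimum of 50 CPM, the MHC class I median (low-AFP with control) reversed to -0.085. Depth limited Afp in particular, at 19 UMIs in all control hepatocyte-like cells.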

Other observations

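The values in this part were chosen after they were seen and are given without explanation. The unnamed and small clusters of the HCC library differed from one another. Cluster 43, with 54 HCC cells and 2 high-AFP cells at a median depth of 24291.5 UMIs, was led by Cyp2a4, Tspan8, Igfbp1, Ly6d and Cdkn2a, and Afp in its HCC cells was at 341 CPM (310.2 to 374). Against control hepatocyte-like cells its HCC cells had 16 of 16 p53 and senescence genes at least 2-fold higher (median 2.44), and 11 of 15 MHC class I genes (median 1.58), while pericentral genes had a median of -1.52 and urea cycle genes of -2.63. Cholangiocyte markers scored first in cluster 43 (1.23) and hepatocyte markers second (0.693), so these medians may compare different cell types. Whether its cells were doublets was not tested further. Cluster 25, with 282 HCC cells, was led by Akr1c18, Afp, Tstd1, Lcn2 and A2ml1. Its HCC cells held 30.3% of the Afp UMIs of all kept HCC cells, at 698 CPM (636 to 764), and their pericentral median was -0.85. Cluster 46, led by Slc1a2, Sfrp2, Car4, Akr1c18 and Nkd1, had a pericentral median of 3.53 and a periportal median of -4.77. Cluster 22, with 327 HCC cells, led by Oat, Glul, Gstm2, Adgrv1 and Gstm3, had complement and coagulation genes at -3.26, with 22 of 23 lower. Afp was thus high both in clusters with higher and in clusters with lower pericentral transcripts than control.

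Interferon transcripts in cholangiocyte-like cells were higher in low-AFP than in control (5 of 22 genes at least 2-fold higher, median 0.54, percentile 100) and lower in high-AFP than in control (3 of 20 lower, median -0.28, percentile 0.86), from 71, 70 and 62 cells in control, low-AFP and high-AFP. Of the control cells 13 lay in cluster 47, and endothelial genes were lower in low-AFP than in control in this class: Kdr (9.62 against 242 CPM, -3.68), Ehd3 (-3.63) and Dnase1l3 (-3.51). They were lower in high-AFP than in control as well (-1.99, -1.74 and -2.06). NK-like cells had cytotoxicity medians of -0.47 in low-AFP (percentile 0.11) and -0.22 in high-AFP, but most control NK-like cells lay in cluster 39, whose leading genes included the T cell gene Tcrg-C2. In T-like cells, which make no albumin, Alb was at 4761, 2317, 1442 and 492 CPM in control, low-AFP, high-AFP and HCC, and Mup20 at 1165, 1557, 4140.5 and 99.5 CPM. Hbb-bs over all kept cells was at 305, 80.8, 675 and 3761 CPM.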
